A study of Arabidopsis thaliana with 12 samples.

How the data were processed

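The data were spot intensities of 12 samples of Arabidopsis thaliana total RNA, 6 from plants grown under PSII-specific light and 6 under PSI-specific light, per the labels. The deposited table held 1 intensity per probe and sample on a linear scale, from 0 to a top value of 99.999999999 that was reached 11 times. How the authors corrected the background, normalized the arrays or set this top value is not given in the sources used here, nor is the kind of array or scanner. If the top value is a ceiling of the measurement, a spot at it has only a lower bound. No value was below 0, and 101 probes were at 0 in every sample and 49 in some samples. Because column sums lay within a narrow range while column medians still differed by 0.158 on the log2 scale, the deposited intensities were taken as scaled by the authors in an unknown way. The scale of the intensities is in arbitrary units, and differences between the light regimes were tested within each probe. Intensity depends on the probe as well as on the transcript, so an order of probes by intensity describes spots and not transcript levels.

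Values were turned to log2(intensity + 0.193), the pseudocount being the 5th percentile of the positive values, and quantile normalized between samples, as set for medians differing by over 0.1. The same rule would have kept a table already normalized between arrays as deposited. Whether this table was so normalized is not known, so values as deposited are given as an alternative. The rules on values, replicates, tests, gene lists and named genes were fixed before the data were examined. The rule on repeat measurements asked that the same pairing of the numbers hold in both groups and that each sample's correlation with its partner exceed its others by over 0.2; the smallest gap found was 0.559. The labels do not state such repeats, so this is an inference from the values. Repeat measurements correlated at 0.992 to 0.996 in level, replicates of a group at 0.977 to 0.989 and replicates of different groups at 0.953 to 0.975. The first principal component of the replicate means carried 55.8% of the variance and separated the groups, and the second carried 19.2%.

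Replicates with the same number in both groups deviated together, with correlations across probes of 0.323, 0.366 and 0.360 between PSI-light and PSII-light replicates 1, 2 and 3. By the rule that all such correlations exceed 0.1, the numbers pair the samples. This pairing comes from the shared replicate numbers in the labels and from the values, since the labels name no shared batch. The design set before the data were examined has no block, and the fit with the replicate number as a block is given as an alternative, beside a result where it changes the call.

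The groups were compared with lmFit and eBayes (trend = TRUE) of limma 3.58.1 in R 4.3.3, two-sided, over all 3439 probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. No probe was filtered out. Gene lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and p-values were adjusted over these 3 lists. Camera compares a list with other probes, while fry asks whether its genes move one way. Ribosomal proteins gave an adjusted p of 0.0206 by fry, the photosystem II list 0.511 and the redox list 0.688. On data simulated with the spread of the real replicates for 3439 probes, 99 of 100 probes changed by a log2 difference of 1 were recovered, and 71 of 100 changed by 0.5, with 6 false calls among 176. The simulated noise was independent between probes and replicates, without the shared deviations of the real replicates. Changes were placed only in probes without a value of 0, and no normalization followed. These rates may therefore not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

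Probes were named from the platform annotation of 2016, which can be out of date. Of the 692 probes with 1 gene, 690 were matched by Entrez identifier to the TAIR10.1 gene table, which gave current symbols; its coordinates were not used because the files name no genome build. Probes with several genes were named for none of them. Of 397 loci on the lists, 22 had a probe of their own, and 1 of these, a ribosomal protein gene, is listed at 0 in every sample and was left out, leaving 21. The genes named are the 12 largest rises and the 12 largest falls among called probes with 1 gene and a stable sign when replicates were left out, or all where fewer passed, the members of the lists with the smallest p (up to 4 each), and the 15 genes set from earlier work.

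Alternatives were values as deposited, median centring, leaving out the dimmest 25% of probes, a pseudocount of 1.93, the replicate block, all 6 samples per group with repeats as a random block (correlation 0.657) or as separate samples, eBayes without trend, robust eBayes, array weights, an exact permutation test per probe, and leaving out each replicate. After seeing the data, removal of a running median over 101 consecutive probe numbers and the inclusion of probes of several genes in lists were added.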

Results

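Transcript levels were measured by array in wild-type Arabidopsis thaliana of the C24 accession grown under light specific for photosystem II (PSII light) or photosystem I (PSI light). The deposited values held 6 samples of each group, each with a spot intensity for 3439 probes. Within both groups, samples numbered 1 and 2, 3 and 4, and 5 and 6 deviated from the group mean together, with correlations between 0.468 and 0.693 across probes, and every other correlation was negative. Each such pair was counted as 1 sample by taking its mean, which left 3 replicates per group. These 3 replicates are called replicates 1, 2 and 3. The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Summed intensity per sample lay between 3642.89 and 3767.52, and the number of arrays limited the precision. Of the probes, 692 were annotated to 1 gene, 870 to several genes, and 1877 were not listed in the annotation used here, so that most differences below carry no gene name.

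The comparison addressed which transcripts differed between plants grown in PSII light and in PSI light. With these 2 regimes alone, a difference cannot be assigned to the photosystem favoured rather than to another property of the light. LHB1B2 (LHCB1.5, AT2G34420), which encodes a light-harvesting chlorophyll a/b protein of the photosystem II antenna, fell from an intensity of 22.3 ± 2.85 in PSI light to 10.03 ± 1.25 in PSII light (SD, n = 3). PSB27 (AT1G03600), a thylakoid lumen protein that takes part in photosystem II assembly and repair, fell from 3.03 ± 0.377 to 1.62 ± 0.247 (SD, n = 3). AT4G35660, of unknown function, fell from 6.37 ± 0.864 to 1.25 ± 0.0994 and AT4G18180, of the pectin lyase-like family, from 1.99 ± 0.248 to 0.632 ± 0.0499 (SD, n = 3). In the other direction AT4G39760, an F-box protein with kelch repeats, rose from 2.26 ± 0.384 to 4.08 ± 0.288 (SD, n = 3).

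Differences were tested with limma on log2(intensity + pseudocount), a scale that understates the change of dim probes. The log2 difference of LHB1B2 was -1.13 ± 0.15 (SE; limma, Benjamini-Hochberg adjusted p = 0.0203), 2.18-fold lower in PSII light. That of PSB27 was -0.82 ± 0.14 (SE; limma, Benjamini-Hochberg adjusted p = 0.0339), 1.77-fold lower. AT4G35660 differed by -2.20 ± 0.12 and AT4G18180 by -1.41 ± 0.09, both with an adjusted p of 0.00248 (limma, Benjamini-Hochberg). Each of these genes was lower in all 3 PSII-light replicates than in any PSI-light replicate. The call of LHB1B2 was lost when any 1 replicate other than PSI-light replicate 2 was left out, with an adjusted p from limma with Benjamini-Hochberg of up to 0.0815 and a log2 difference between -1.22 and -1.01. The same 5 omissions ended the call of PSB27, with an adjusted p of up to 0.125 and a log2 difference between -0.93 and -0.72 (limma, Benjamini-Hochberg), and a fit without an intensity trend gave PSB27 an adjusted p of 0.0544. LHB1B2 belongs to a family of near-identical Lhcb1 copies, and a probe for it can also detect its relatives.

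Among probes annotated to a single gene, 12 fell and 5 rose in PSII light, and all 17 are named here. AT3G04210, a TIR-NBS protein of the disease resistance family, fell by 1.08 on the log2 scale (adjusted p = 0.00467, limma with Benjamini-Hochberg). AT5G11550, an armadillo-repeat protein, fell by 0.91 and AT3G50130 by 0.79, with adjusted p of 0.00466 and 0.00467 (limma, Benjamini-Hochberg). These 3 genes, AT4G35660 and AT4G18180 kept their calls whichever 1 replicate was left out. AT-HF (HISN4, AT4G26900), an enzyme of histidine biosynthesis, fell by 0.55 (adjusted p = 0.0134, limma with Benjamini-Hochberg), and its call was lost without PSI-light replicate 1, PSII-light replicate 1 or PSII-light replicate 3, with an adjusted p of up to 0.0671. Falls were also found for AT2G39100 (log2 difference -0.59), AT2G46630 (-0.33), AT4G34310 (-0.33) and AT3G61680 (-0.11), the last of which encodes the plastid lipase PLIP1. AT4G39760 rose by 0.84 on the log2 scale (adjusted p = 0.0238, limma with Benjamini-Hochberg). AT4G31930, of the mitochondrial glycoprotein family, rose by 0.42, AT5G27560 by 0.39, AT3G56130, which carries a biotin/lipoyl attachment domain, by 0.28, and AT1G07040 by 0.13. The probe of AT4G31930, number 2396, precedes called probe 2397 (0.49) and the much brighter uncalled probe 2398 (1.21). Signal from a neighbouring spot was therefore not excluded for AT4G31930. The mean intensities of AT3G61680 (0.147) and AT1G07040 (0.192) lay below the pseudocount of 0.193 and that of AT3G56130 (0.215) just above it, and all 3 belonged to the dimmest 25% of probes.

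The calls of AT4G31930, AT5G27560, AT3G56130, AT2G39100, AT2G46630 and AT4G34310 were each lost on leaving out any 1 of the 6 replicates, with adjusted p from limma with Benjamini-Hochberg reaching 0.162 for AT2G46630. Those of AT4G39760, AT1G07040 and AT3G61680 were lost on leaving out any 1 replicate other than PSI-light replicate 2, with an adjusted p of up to 0.106, 0.128 and 0.0985. With the replicate number as a block, 4 calls ended, those of AT4G39760 (adjusted p = 0.0667), AT3G56130 (0.0741), AT2G46630 (0.0677) and AT4G34310 (0.0678), by limma with Benjamini-Hochberg. On values as deposited, without quantile normalization, the calls of AT4G31930, AT3G56130, AT1G07040, AT2G39100, AT2G46630, AT4G34310 and AT3G61680 ended, with adjusted p from limma with Benjamini-Hochberg between 0.0531 and 0.120. The calls of AT1G07040 and AT3G61680 also ended with median centring (adjusted p = 0.306 and 0.149), with robust eBayes (0.152 and 0.173) and without an intensity trend (0.0694 and 0.0870), by limma with Benjamini-Hochberg. Without an intensity trend those of AT3G56130 (0.0575) and AT2G39100 (0.0573) ended as well. All 17 genes kept the sign of their difference whichever 1 replicate was left out. The rule for naming required this, and groups that do not overlap cannot change sign in such a fit, so it adds no support.

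**Figure D1:**
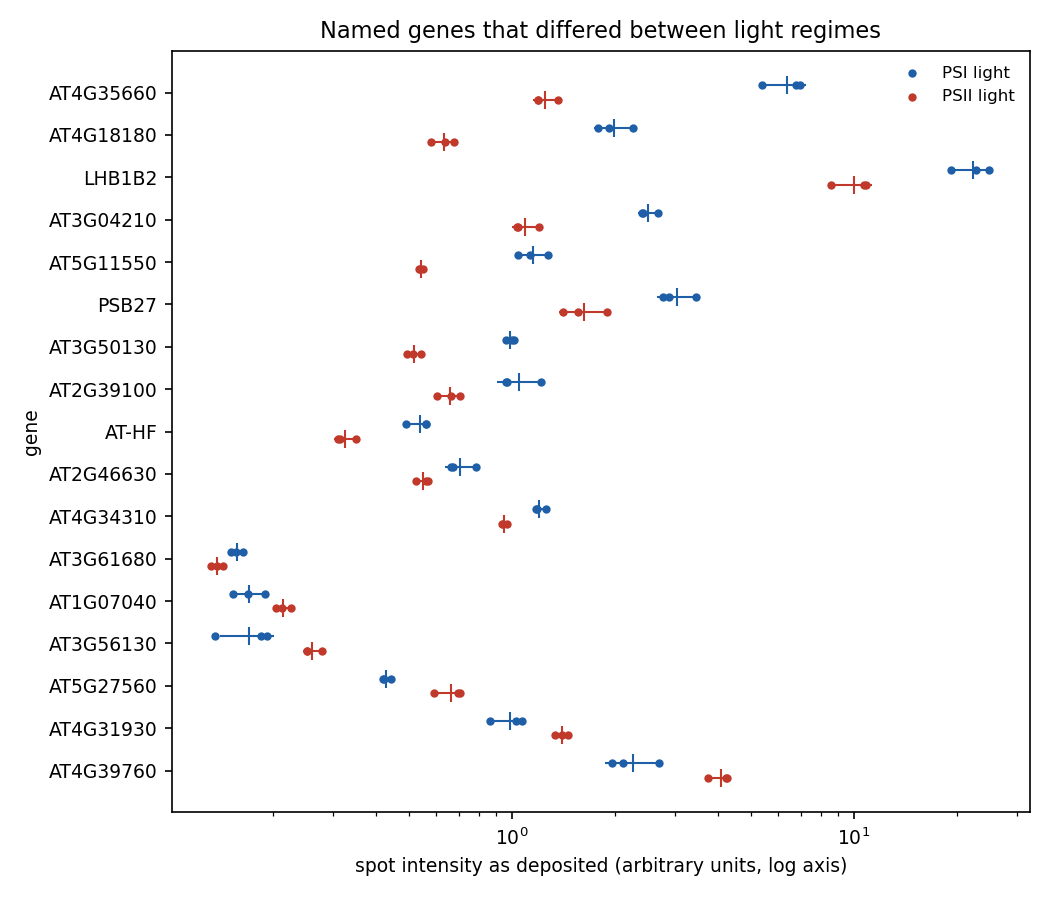
Spot intensity as deposited (arbitrary units, log axis) of the 17 named genes in the 3 PSI-light replicates (blue) and the 3 PSII-light replicates (red), with points for replicates, a vertical tick for the mean and a horizontal bar for the SD. LHB1B2 lies at 22.3 in PSI light and 10.03 in PSII light, and for each gene the points of the groups do not overlap.

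Over all 3439 probes, 108 passed an adjusted p under 0.05 (3.14%; limma with Benjamini-Hochberg), of which 26 were higher and 82 lower in PSII light. All 19 called probes with a log2 difference of at least 1 in size were lower in PSII light, and the called probes ranged from -2.32 to 0.88. The median log2 difference was -0.68 among the called probes that were lower and 0.44 among those that were higher. At an unadjusted p under 0.05 limma counted 766 probes, 391 higher and 375 lower, so the excess of lower probes held for the called set and not for the wider one. An exact permutation test per probe cannot go below p = 0.1 with 3 replicates against 3, and called 0 probes after Benjamini-Hochberg adjustment. Groups did not overlap for 947 probes (27.5%), against 10% by chance if replicates are exchanged freely, which ignores their pairing by number. The count changed when 1 replicate was left out, which also leaves fewer samples to test with. It was 20 without PSI-light replicate 1, 140 without PSI-light replicate 2, 28 without PSI-light replicate 3, and 31, 41 and 22 without PSII-light replicates 1, 2 and 3. The replicate number as a block gave 103 probes, of which 69 were among the 108.

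**Figure D2:**
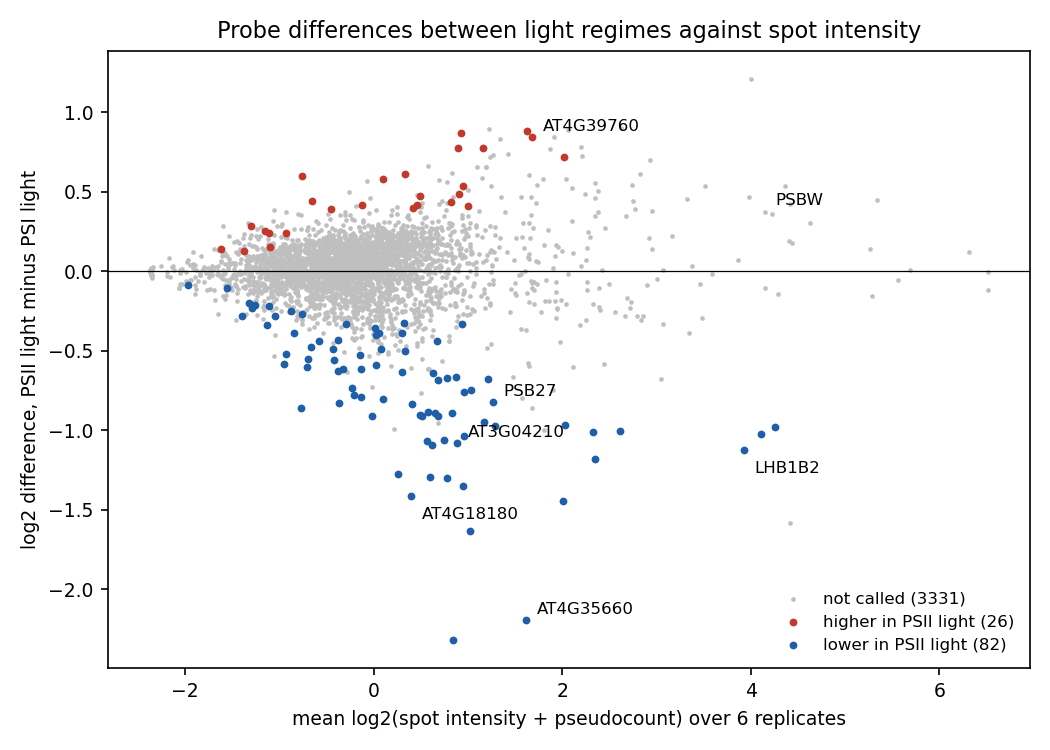
Log2 difference (PSII light minus PSI light) of each probe against its mean log2(spot intensity + pseudocount) over the 6 replicates after quantile normalization, with probes called higher in PSII light in red (26), called lower in blue (82) and others in grey. LHB1B2 lies at -1.13 and AT4G35660 at -2.20, while AT4G39760 lies at 0.84; PSBW, at 0.38, is not called.

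Gene lists for 24 plastid and control groups were fixed before the data were examined, and 21 of their genes had a usable probe of their own. Of these, 0 rose and 2 fell, LHB1B2 of the photosystem II antenna and PSB27 of the photosystem II subunits. The photosystem II list held 3 measured genes, of which PSB27 alone passed the test over all probes. PSBW, a small intrinsic subunit, was at 16.6 ± 1.42 in PSI light and 19.6 ± 2.44 in PSII light (SD, n = 3), a log2 difference of 0.38 ± 0.12 (SE; limma, Benjamini-Hochberg adjusted p = 0.145). That difference depended on scaling, being 0.23 on values as deposited and 0.17 with median centring (adjusted p = 0.381 and 0.633, limma with Benjamini-Hochberg). It passed with repeat measurements as a random block (0.0148) and with all 6 as separate samples (0.00135). PSBY, another small subunit, had a log2 difference of -0.25 ± 0.13 (SE; limma, Benjamini-Hochberg adjusted p = 0.306). Adjusted over the list alone, 2 of the 3 photosystem II genes passed, PSB27 with the lower and PSBW with the higher intensity in PSII light. PSBY passed this adjustment (limma, Benjamini-Hochberg) with median centring (adjusted p = 0.0287) and with the running median over probe numbers removed (0.0426). It also passed with repeat measurements as a random block (0.0395), all 6 as separate samples (0.0178) and without PSII-light replicate 1 (0.0293). On the same adjustment by limma with Benjamini-Hochberg, PSBW did not pass on values as deposited (adjusted p = 0.175), with median centring (0.401), with the replicate number as a block (0.0679), or without PSI-light replicate 1, PSI-light replicate 2 or PSII-light replicate 3 (up to 0.103). As a set the list, with a median log2 difference of -0.25, did not pass limma's camera, which tests a shift in a common direction (adjusted p = 0.420). With an estimated correlation camera gave an adjusted p of 0.504. For differences in either direction limma's fry gave an unadjusted p of 0.0029 for this list. It gave 0.00366 for the plastid ribosomal proteins, which had 0 calls, and 0.573 for the redox list. PSB27 was already called on the same values, so the fry result adds no separate support.

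The plastid ribosomal proteins, which serve translation inside the organelle, had 5 measured genes, and all 5 had negative log2 differences with a median of -0.17. None passed the test singly (0 of 5, and 0 adjusted over the list alone), the nearest being AT4G01310 at -0.19 ± 0.06 (SE, limma, Benjamini-Hochberg adjusted p = 0.170). Adjusted over the list alone, the replicate block gave 2 passes and all 6 as separate samples gave 3. The fit without an intensity trend and the random block gave 1 each, AT4G01310 (adjusted p = 0.0489 and 0.0305, limma with Benjamini-Hochberg). AT1G64510 was at -0.18, AT3G13120 at -0.17, AT3G54210 at -0.10 and AT1G29070 at -0.08. The list as a set was lower in PSII light by limma's camera with a preset correlation (adjusted p = 0.0397), and that call was lost with an estimated correlation (adjusted p = 0.194). The estimate was -0.038, below the preset 0.01, so a higher correlation among these genes does not account for the loss. It was also lost without between-array normalization (adjusted p = 0.0753), with median centring (0.0913), without the dimmest 25% of probes (0.211), and without PSI-light replicate 2 (0.128), PSI-light replicate 3 (0.0857), PSII-light replicate 2 (0.0518) or PSII-light replicate 3 (0.0703).

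The plastid redox and antioxidant list had 3 measured genes and 0 calls, over all probes and adjusted over the list alone. The peroxiredoxin gene AT3G52960 had a log2 difference of 0.11, the NADPH-dependent thioredoxin reductase gene NTRC one of 0.00056, and AT2G04700, a ferredoxin-thioredoxin reductase subunit, one of -0.11. The median and mean of the list were above 0 while camera gave a downward direction, with an adjusted p of 0.812 (limma's camera). In the Calvin cycle list PRK, phosphoribulokinase, had a log2 difference of 0.31 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.320) and SBPASE, sedoheptulose bisphosphatase, one of 0.25 ± 0.11 (SE; adjusted p = 0.237). PSAN, the measured gene of the photosystem I subunits, had a log2 difference of 0.11 ± 0.06 (SE; limma, Benjamini-Hochberg adjusted p = 0.323), which was 0.03 with median centring, 0.07 with the larger pseudocount and 0.07 with a running median over probe numbers removed. In tetrapyrrole biosynthesis CHLM, a magnesium protoporphyrin methyltransferase, was at 0.06 and AT1G74470, geranylgeranyl reductase, at -0.07. In fatty acid synthesis AT1G24360 was at 0.06 and FATB, an acyl-ACP thioesterase, at -0.10. In amino acid biosynthesis AT3G23940 was at 0.21 and AT3G58610 at -0.00021, the latter at 0.06 on values as deposited. None of these genes passed the test over all probes or adjusted over the list alone in the 3 against 3 comparison on quantile-normalized values. AT3G23940 passed with repeat measurements as a random block (adjusted p = 0.0301, limma with Benjamini-Hochberg) and, like SBPASE, with all 6 as separate samples. Of 15 genes set for reporting from earlier work on light quality, LHCB1.5 was the 1 with a probe annotated to it alone, and 15 of the 24 lists had no measured gene and were not analysed here.

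**Figure D3:**
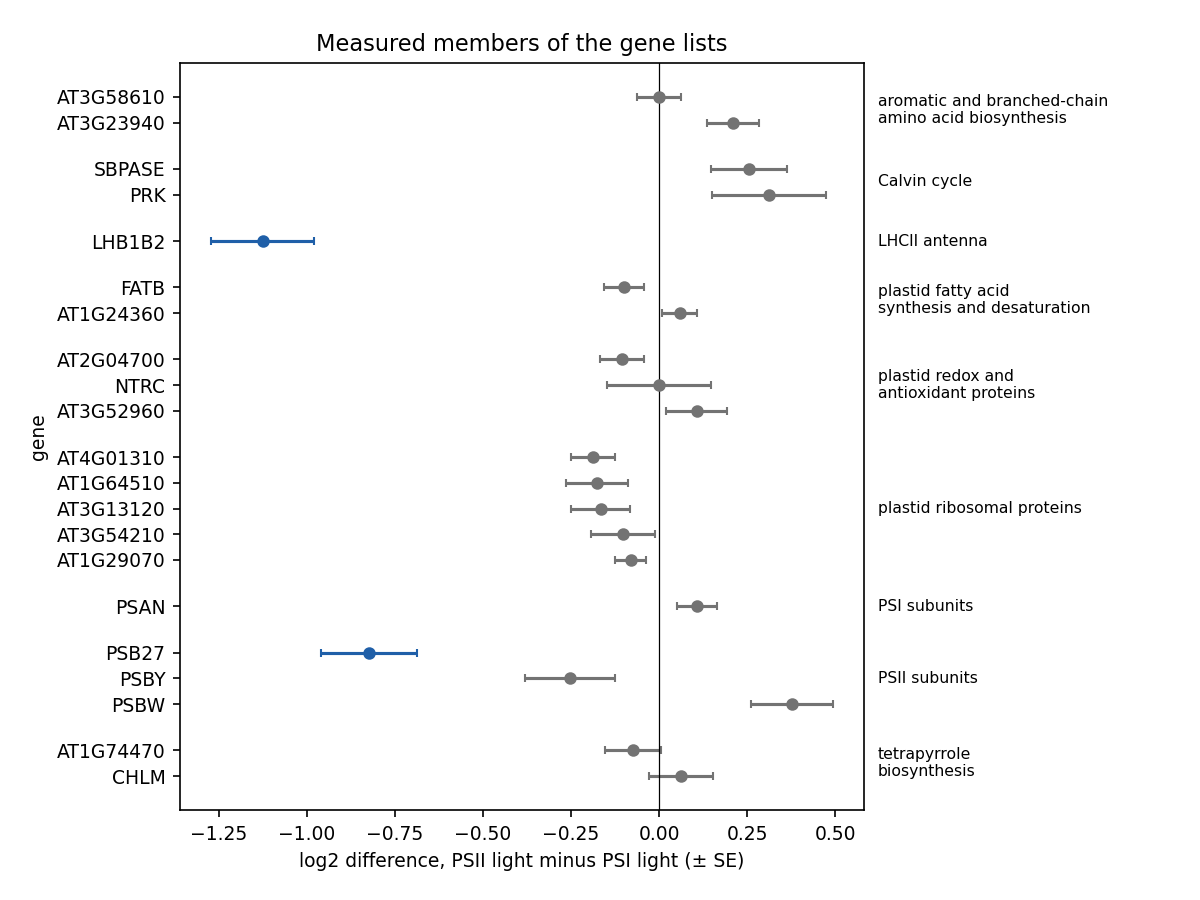
Log2 difference (PSII light minus PSI light) with its SE for the 21 measured genes of the fixed lists, grouped by list, with genes that passed the test over all probes in blue. LHB1B2 at -1.13 and PSB27 at -0.82 are the 2 blue points, and the 5 ribosomal protein genes all lie below 0.

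Of the 108 called probes, 30 were annotated to several genes and 61 were not listed in the annotation, so that no gene is named for them. Among those not listed, the largest rises were at probes 2718 (log2 difference 0.87) and 4188 (0.78), and the largest falls at probes 922 (-1.64) and 874 (-1.45), all past the test in limma with Benjamini-Hochberg. With the replicate number as a block the call of probe 874 ended (adjusted p = 0.0510, limma with Benjamini-Hochberg). Each of the 4 calls was lost without PSI-light replicate 1 or PSII-light replicate 3, and some without PSI-light replicate 3, PSII-light replicate 1 or PSII-light replicate 2, with adjusted p from limma with Benjamini-Hochberg of up to 0.0805 for probe 2718, 0.0805 for 4188, 0.0696 for 922 and 0.0959 for 874. Probe 922 went from an intensity of 3.52 ± 0.895 in PSI light to 0.979 ± 0.0669 in PSII light (SD, n = 3). A probe annotated to 3 genes of the photosystem II antenna list had a log2 difference of -0.25 ± 0.10 (SE; limma, Benjamini-Hochberg adjusted p = 0.225).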

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

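The removal of a running median over probe numbers and the lists with probes of several genes were chosen after seeing the data; the cause of the changes below was not tested except where the number of samples or probes accounts for it. The main count of 108 probes (26 higher, 82 lower) was 92 on values as deposited, 109 with a pseudocount of 1.93, 126 without trend and 103 with the replicate block, all within 1.5 times. It became 228 (54 higher, 174 lower) with median centring, 228 (73 and 155) without the dimmest 25% of probes, 232 (84 and 148) with array weights, 173 (50 and 123) with robust eBayes, 223 (60 and 163) with the running median removed, 365 (158 and 207) with repeat measurements as a random block, 916 (478 and 438) with all 6 as separate samples, which counts repeats as independent, and 0 by the exact permutation test per probe, whose smallest p is 0.1. Leaving out 1 replicate, which also leaves fewer samples, gave 20 to 140 probes, 1 to 52 higher and 18 to 88 lower. The share of calls higher in PSII light was 24.1%, against 28.3% as deposited and 23.7% with median centring. It was 43.3% with repeat measurements as a random block and 52.2% with all 6 as separate samples. Leaving out 1 replicate gave from 3.57% (without PSI-light replicate 3) to 37.1% (without PSI-light replicate 2).

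The shift of the ribosomal list lost its call, with the same sign, as deposited (median -0.1016), with median centring (-0.162), without the dimmest probes (-0.1664), with the estimated correlation (-0.1664) and with the running median removed (-0.1328, adjusted p = 0.0550); leaving out replicates gave -0.1989 to -0.1234. The redox list's median turned sign with probes of several genes (-0.06618), median centring (-0.004879) and the running median removed (-0.006765), as did NTRC in the last 2 (the same values), and ranged from -0.1045 to 0.09402 without single replicates, and it was -0.08834 without PSII-light replicate 1. The photosystem II list ranged from -0.3645 to -0.123. AT3G58610, at -0.00021, turned sign as deposited (0.06441), with median centring (0.004032), the pseudocount of 1.93 (0.0001945) and the running median removed (0.02171), and ranged from -0.04691 to 0.02554 without single replicates. NTRC then ranged from -0.1265 to 0.09402 and CHLM from -0.0296 to 0.12. Of the 18 genes without a call, the random block called 2, AT3G23940 (adjusted p = 0.0301) and PSBW (0.0148), and all 6 as separate samples 4, AT3G23940 (0.00758), SBPASE (0.0249), AT4G01310 (0.00507) and PSBW (0.00135), by limma with Benjamini-Hochberg. Of the 17 called genes, 13 kept the call with the replicate block, 10 as deposited, 15 with median centring, 15 with robust eBayes, 15 with the running median removed, 14 with the random block, 16 with all 6 as separate samples (AT3G61680 lost it, 0.128), 16 with the pseudocount of 1.93, 12 without trend, 17 with array weights and 5 in every fit without 1 replicate; 14 were tested and kept it without the dimmest 25%. AT1G07040 and AT3G61680 lost it with median centring (adjusted p = 0.306 and 0.149), robust eBayes (0.152 and 0.173), the random block (0.220 and 0.595) and the running median removed (0.233 and 0.156), by limma with Benjamini-Hochberg. With the pseudocount it was AT2G39100 (0.0531) that lost it, and with the random block also AT3G56130 (0.107); the block ended the calls of AT4G39760, AT3G56130, AT2G46630 and AT4G34310 and of probes 874, 2677 and 2689, and of no other gene, list or single probe named in the text, apart from the pass of PSBW adjusted over its list alone (0.0679). Dim probes limit the data: the pseudocount compresses their differences. With the pseudocount of 1.93 the log2 difference was -1.01 for LHB1B2, -0.61 for AT4G18180 and -0.48 for PSB27. For AT4G31930 it was 0.18 and for AT3G56130 0.053.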

Other observations

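The NDH genes, the scaling comparison, the brightness comparison and the regrouping of samples were chosen as tests only after the result was seen; the tests with a running median over probe numbers were set before their results. CCL, a gene with a rhythmic transcript, was at 5.37 ± 0.757 in PSI light and 7.99 ± 1.03 in PSII light (SD, n = 3), a log2 difference of 0.54 that did not pass adjustment (limma, Benjamini-Hochberg adjusted p = 0.0839). XERICO, a RING protein linked to abscisic acid, was at 2.15 ± 0.327 and 2.77 ± 0.244 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.110). FZL, a membrane-remodelling protein of thylakoids, had a log2 difference of 0.41 (limma, Benjamini-Hochberg adjusted p = 0.145). These 3 genes were picked after their values were seen.

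Genes of the plastid NDH complex, which carries cyclic electron flow, and of factors linked to it had log2 differences of 0.22 (NdhS), 0.20 (CRR41), 0.15 (CRR21), 0.09 (NdhN) and 0.02 (PIFI), all 5 positive with 0 called. The hypothesis that this complex shifts together in PSII light was put to limma's camera, which gave p = 0.0652 with the preset correlation and p = 0.133 with an estimated one. Because the genes were gathered after their values were seen, this test decides nothing and the hypothesis stays open.

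More called probes were lower than higher in PSII light (82 against 26; exact two-sided binomial p = 6.14e-08, which treats probes as independent). If the added quantile normalization were the cause, the excess would be expected to vanish without it. Without it, 71.7% of calls were lower on values as deposited (exact 95% interval 61.4 to 80.6) and 76.3% with median centring. Of these calls, 82 and 102 were also calls of the main values, so the comparisons are not independent. Both settings keep any scaling made by the authors, so they cannot test it, and scaling between arrays stays open as a cause. With a running median over probe numbers removed, 73.1% of calls were lower (66.8 to 78.8), but no layout of the array was used here, so a smooth trend in position on the array stays open. The excess was smaller with repeat measurements as a random block (56.7%) and absent with all 6 as separate samples (47.8%). A biological explanation by the light regimes stays open and was not tested. Among all probes, 20 were lower and 1 higher by at least 1 on the log2 scale.

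Called probes seemed on inspection to lie 1 or 12 probe numbers apart, a spacing picked from the list of calls. The count of such pairs was 9, against a mean of 5.21 in 10000 random placements (central 95% 1 to 10; permutation p = 0.0773), so the spacing was not above chance in the main values. With the running median removed there were 34 pairs among 223 calls (random range 14 to 32), but 103 of the 108 calls from which the spacing was picked are among them, so this count decides nothing. Of the 9 pairs, 0 had a 4-fold gap in brightness (0%, exact 95% interval up to 33.6%). These pairs hold called probes only, so a brighter neighbour without a call could not appear in this count. Uncalled probe 2398 went from 10.9 in PSI light to 24.4 in PSII light. It follows called probes 2396, that of AT4G31930, and 2397 in number, whose mean intensities were 1.19 and 1.71. What probe numbers stand for on the array is not given in the sources used here, so neither a position trend nor signal spreading from a much brighter neighbour was excluded. Of the 9 pairs, 7 moved the same way. Since 82 of the 108 calls were lower, many pairs would share a direction without any link. Among the 7 were the LHB1B2 probe, 2665 (-1.13), with probe 2677 (-1.03), and probe 2677 with probe 2689 (-0.98), each 12 numbers apart. Their mean intensities were 16.2, 17.6 and 19.2. Probes 2677 and 2689 are not listed in the annotation. The call of LHB1B2 is thus part of this unresolved spacing. With the replicate block the calls of probe_2677 and probe_2689 ended (adjusted p = 0.0510 and 0.0532, limma with Benjamini-Hochberg).

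The 6 replicates can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 108 probes and was the 1 split with as many. The highest other called 0, also among the 3 other splits that part all 3 pairs. Every other split mixes both light regimes in each group, so a difference between the regimes widens the spread within its groups and lowers its count. The comparison therefore cannot tell whether chance gave the 108 calls.

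PSI-light replicate 2 lay nearest to the PSII-light replicates on the first principal component (3.33, against 7.09 and 9.23 for the other PSI-light replicates), had the lowest array weight (0.585), and its omission raised the count of calls to 140. PSII-light replicate 2 had the next lowest weight (0.675). On the second component replicate 2 of both groups lay below 0 (-6.29 in PSI light, -4.43 in PSII light) and all other replicates above it. Among the 344 probes with the highest spot intensity, 10 were called higher and 25 lower.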
